A study of Drosophila melanogaster with 4 samples.

How the data were processed

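Chromatin from the heads of wild-type Oregon-R adults of Drosophila melanogaster was crosslinked with formaldehyde, sonicated and immunoprecipitated with the wa191 antibody against HP1a, per the labels' protocols. The series holds 2 ChIP libraries and 2 input libraries, 1 input for each ChIP replicate. Input signal and reads were not analysed here. The enriched regions of each ChIP library, called clusters here, and a combined set for the series were used.

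Per the submitters' processing notes, Bowtie 0.12.7 was among the tools used, and per the file headers all coordinates are on FlyBase r5. The caller of the clusters, its threshold, the treatment of reads that map to several places and the way in which the replicates were combined are not given in the sources used here. Each cluster was deposited with a start, an end and a score, whose scale is not given in the sources used here. The score was above 0 for regions named as enriched and below 0 for 2 regions of the combined set named as depleted, so it was read only as the authors' own measure of ChIP over input and used to describe and rank regions within a list. In the combined set, 61 clusters with a score above 2.9 shared 7 values whose spacing was that of log2 of ratios of whole numbers, within 0.001. The shortest deposited cluster was 1301 bp in both replicate lists and 1001 bp in the combined set, so the 3 lists were not made with 1 length limit. The lists give no read counts, so the depth per library is unknown and no counting interval can be given. A base outside all clusters may be unbound, unmappable or too thinly read, and these cases cannot be separated in a list of regions.

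The 2 depleted regions were left out of all coverage values. Clusters that ran past the end of a sequence (3 in replicate 1, 4 in replicate 2 and 5 in the combined set) and 1 start at position 0 were clipped to the sequence lengths in the file headers. Coverage was the share of the bases of a region that lay inside clusters. The analysed sequences were the 13 that held a cluster, 139.7 Mb in all. The sequence named Uextra, of 29004656 bp, held 0 clusters in every list and was left out.

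The sequences were divided into 5 classes, set before the data were examined: the placed heterochromatic scaffolds with the unplaced sequence U, the centromere-proximal 1 Mb of 2L, 2R, 3L, 3R and X (the high-coordinate end of 2L, 3L and X and the low-coordinate end of 2R and 3R), chromosome 4, the rest of the arms (distal arms), and YHet. The coverage of each class was tested against 10000 circular shifts of the whole cluster list along the joined sequences, a two-sided permutation test with Benjamini-Hochberg adjustment over 10 tests. The overlap of the replicates was measured as the share of clusters with at least 1 bp in the other list and as the Jaccard index of covered bases (shared bases over all covered bases), tested one-sided against 1000 circular shifts within each sequence and adjusted over 6 tests. These tests compare lists of regions and take no account of the spread between flies. The labels do not say whether the replicates came from separate cages of flies, so the SD over 2 replicates may be technical. Scores of the replicates were compared only as a correlation across regions, and their levels were not compared between lists. The correlation was taken across combined-set clusters that met both lists, each with the length-weighted mean score of the replicate clusters inside it.

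The regions named were chosen by a rule fixed before the data were examined: the 10 longest combined-set clusters on the distal arms and the 5 highest-scored combined-set clusters of each class. Equal scores were ranked by sequence name and position. Scores of 4.09 and 3.68 were shared by 4 and 14 combined-set clusters, so the last places of a class can depend on that order. Comparisons of the X with the autosomal arms in windows of 1 Mb, the borders of the pericentric blocks, the arm ends, the gaps of chromosome 4 and the islands beyond 2 Mb were chosen after seeing the data. The X comparison used a two-sided permutation test with 100000 permutations of the windows. Alternatives were only the clusters at or above the median score of each list, clusters under 1000 bp apart merged, a minimum length of 1000 bp, pericentric windows of 0.5 Mb and 2 Mb, 50% of a cluster as the overlap that counts as shared, and each replicate alone.

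The 3 planned results on genes (coverage of gene bodies, fixed gene lists, and start sites against gene bodies) were not run, since no annotation on r5 was at hand and coordinates were not converted between builds. Regions are therefore given by position without gene names. On simulated lists with no relation to each other, 2 of 40 overlap tests, 0 of 40 chromosome 4 tests and 1 of 40 window tests fell under a p of 0.05, and planted overlap, planted chromosome 4 coverage and a planted X difference were each recovered. The simulated clusters were spread evenly over the sequences, and the simulated windows were independent draws. The real lists are clumped and neighbouring windows are related. These runs therefore do not give the error rates or the power of the tests on the real lists. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.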

Results

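HP1a, the chromodomain protein of Drosophila heterochromatin that binds methylated histone tails, was mapped by ChIP-seq in nuclei from the heads of wild-type Oregon-R adults. The profile consisted of 2 ChIP libraries, each with an input library that the labels assign to its cluster list, and a combined set made by the authors. Replicate 1 held 3564 clusters covering 23.5 Mb and replicate 2 held 4467 clusters covering 22.8 Mb. The mean was 4016 ± 639 clusters (SD, n = 2) covering 16.6% ± 0.351 (SD, n = 2) of the analysed sequence. The median cluster length was 2796 bp in replicate 1 and 2566 bp in replicate 2, and the longest clusters reached 124276 bp and 98139 bp. The combined set held 5583 clusters over 29.99 Mb. The series has 1 tissue and 1 antibody, so the comparisons that follow are between parts of the genome and between the replicates.

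The first question was where HP1a clusters lay along the chromosomes. Heterochromatic and unplaced sequence, the centromere-proximal ends of 2L, 2R and 3L, chromosome 4 and YHet were each covered over most of their length. The proximal ends of the 3R and X arm sequences in r5 were not, and the distal arms were covered thinly. The Het scaffolds and the unplaced sequence U were covered to 67.0% ± 5.90 (SD, n = 2), the proximal 1 Mb of the 5 arms to 57.6% ± 1.16 (SD, n = 2), chromosome 4 to 78.0% ± 4.59 (SD, n = 2) and YHet to 60.6% ± 14.0 (SD, n = 2). The distal arms were covered to 5.55% ± 0.700 (SD, n = 2), although they made up 114 Mb of the sequence. They were covered to 1.71% when only clusters at or above the median score of each list were kept. By construction that cut falls mostly on distal clusters, whose scores were low. This class takes in densely covered sequence of 2R and 3L just past 1 Mb. With a pericentric window of 2 Mb the distal arms were covered to 4.65%. Relative to the distal arms of the same replicate, coverage was 12.2 ± 2.60 times higher on Het and unplaced sequence, 10.5 ± 1.53 times higher in the proximal class and 14.2 ± 2.62 times higher on chromosome 4 (SD, n = 2). Of all covered bases, 57.4% in replicate 1 and 52.2% in replicate 2 lay on Het and unplaced sequence, and 24.5% and 30.2% lay on the distal arms.

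In the circular-shift permutation test, the excess on Het and unplaced sequence passed the threshold in both replicates (adjusted p = 0.00033 in each, built on the smallest p of 0.0001 that the shifts can give). The proximal class also passed this permutation test (adjusted p = 0.0077 in replicate 1 and 0.0016 in replicate 2), as did the deficit on the distal arms (adjusted p = 0.00033 and 0.0005). Chromosome 4 did not pass after adjustment (permutation p = 0.043 and 0.049, adjusted p = 0.061 in both), nor did YHet (adjusted p = 0.12 and 0.14). Both are single sequences, of 1.35 Mb and 0.347 Mb, so that each test rests on 1 short stretch. The shifts also bring other densely covered sequence, such as U and the Het scaffolds, onto each stretch. A short dense sequence is therefore unlikely to pass. The test does not set chromosome 4 or YHet against the distal arms alone.

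**Figure D1:**
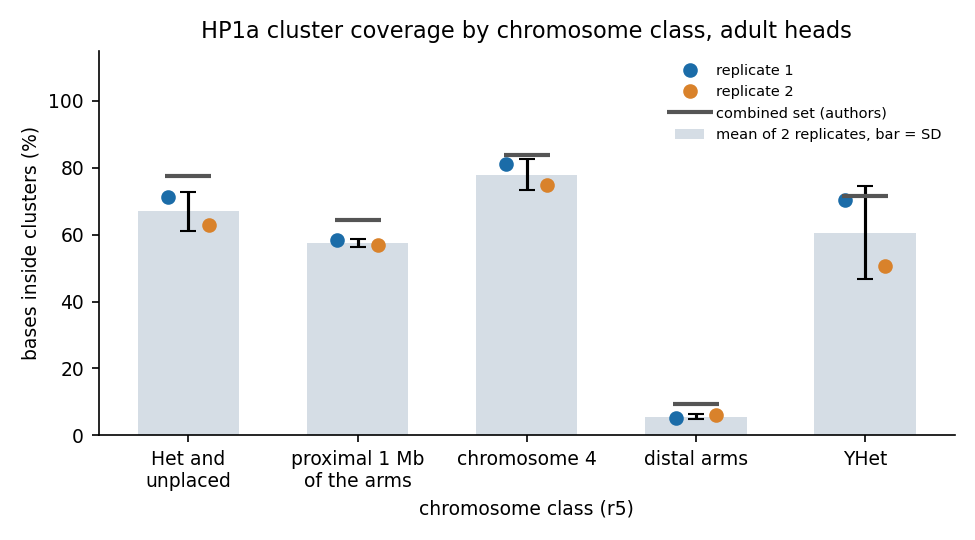
Share of bases inside HP1a clusters (percent, vertical axis) for the 5 chromosome classes on r5 (horizontal axis). Bars are means of the 2 replicates with the SD, circles are the replicates and dashes are the authors' combined set. The distal arms lie at 5.06% and 6.05% in the replicates, and every other class lies above 50%.

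Among the placed scaffolds, 3LHet was the most covered, at 82.2% ± 4.10, followed by 3RHet at 76.2% ± 4.01, 2RHet at 71.2% ± 2.37 and 2LHet at 67.1% ± 4.04 (SD, n = 2). XHet lay lower, at 49.3% ± 2.77 (SD, n = 2). The unplaced sequence U was covered to 65.6% in replicate 1 and 54.0% in replicate 2, and YHet to 70.5% and 50.7%. On these 2 sequences the replicates lay further apart than on the placed Het scaffolds. The 5 combined-set clusters ranked highest in the Het and unplaced class all lay on U, with scores from 4.09 to 4.32. The last places fell within a tie at 4.09. Of these 5 regions, both replicates had clusters in the 2 at 7047530 to 7052996 and 5971858 to 5976320, replicate 2 alone had 1 in the region at 7563152 to 7565296, and neither had any in the other two, which shared a score of 4.09. On YHet, 3 of the 5 highest-scored regions were met by both replicates, the longest of them from 22644 to 45448 with a score of 2.16.

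The proximal ends of the arms differed from each other. A continuous block of 100 kb bins, each covered to at least 50% in both replicates, extended 0.9 Mb from the proximal end of 2L, 1.6 Mb from that of 2R and 1.5 Mb from that of 3L. The blocks ended near position 22111545 on 2L, 1600000 on 2R and 23043558 on 3L. Coverage inside the 2R block was 89.7% in replicate 1 and 86.5% in replicate 2, and in the next 200 kb it was 1.29% in both. On 2L it fell from 85.5% and 82.3% inside the block to 13.8% and 8.88% in the next 200 kb, and on 3L from 88.4% and 85.0% to 21.4% and 18.9%. The ends of 3R and X in r5 had no such block. The Het scaffolds are sequences apart from the arms: 3RHet was covered to 79.0% and 73.3%, and XHet to 47.3% and 51.3%. A missing block at the r5 end of an arm therefore does not show a lack of HP1a nearer the centromere. The proximal 1 Mb of 2L was covered to 79.4% and 75.8%, that of 2R to 89.0% and 85.5% and that of 3L to 89.7% and 85.6%. The proximal 1 Mb of 3R was covered to 10.4% and 10.1%, and that of X to 23.6% and 26.9%. The densest part of proximal X lay 0.5 to 0.9 Mb from its end, at 21522828 to 21922827, where 46.5% and 48.9% of the bases were covered. The highest-scored proximal regions were the clusters on 2R at 755342 to 769830 (score 3.17), 129434 to 143264 (score 3.08), 356398 to 371874 (score 2.94) and 116108 to 124562 (score 2.94), each at least 88% covered in both replicates, and a 1125 bp cluster on 3L at 24129632 that neither replicate had.

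**Figure D2:**
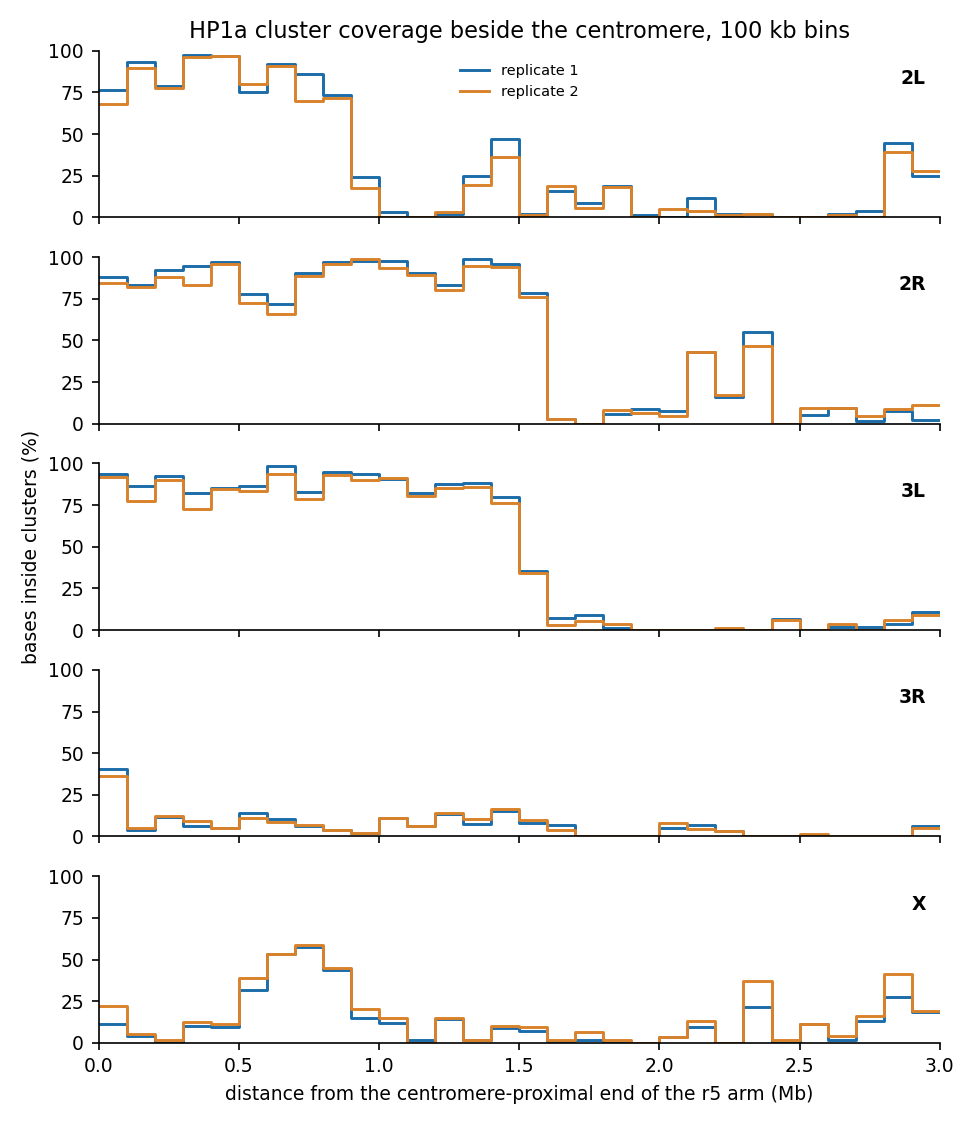
Share of bases inside HP1a clusters (percent, vertical axes) in 100 kb bins against the distance from the centromere-proximal end of each r5 arm (Mb, horizontal axis), with a line for each replicate. The blocks on 2L, 2R and 3L end 0.9, 1.6 and 1.5 Mb from the end, and 3R and X have no block that starts at the end.

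Chromosome 4, the small chromosome whose genes lie within HP1a-rich chromatin, was covered to 81.2% in replicate 1 and 74.7% in replicate 2. Replicate 1 split it into 53 clusters and replicate 2 into 107. Bases outside the clusters of both replicates made up 18.0% of the chromosome, 244 kb in 55 gaps, and the 6 longest gaps held 137 kb of that. The longest gap ran from 507981 to 545228 (37.2 kb), followed by 991224 to 1019451 (28.2 kb), 424114 to 446339 (22.2 kb) and 838349 to 858028 (19.7 kb). The combined set covered 3.80%, 26.4%, 2.07% and 19.2% of these 4 gaps. The highest-scored regions lay at both ends of the chromosome, at 7576 to 11612 (score 4.05), 16 to 6542 (score 3.41), 1325372 to 1336112 (score 3.08) and 1338378 to 1348770 (score 2.98), and each was met by both replicates. The remaining region of the top 5, 1001 bp from 101544, was met by neither.

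**Figure D3:**
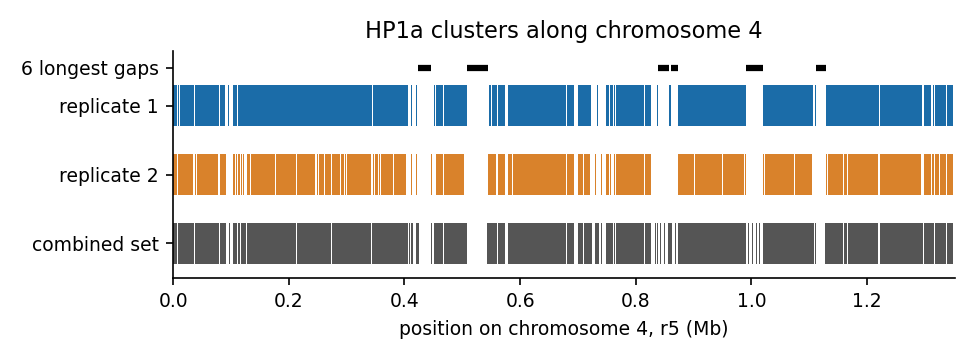
HP1a clusters along chromosome 4 (position in Mb on r5, horizontal axis) in each replicate and in the combined set, with the 6 longest gaps shared by both replicates marked above. The longest gap spans 37.2 kb, and replicate 2 breaks the covered stretches into 107 clusters against 53 in replicate 1.

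Distal arm clusters were many, short and low in score. Replicate 1 had 1780 and replicate 2 had 2288, a mean of 2034 ± 359 (SD, n = 2). Their median length was 2103 bp in replicate 1 and 2080 bp in replicate 2. Their median score was 0.75 in replicate 1 and 0.74 in replicate 2, against 2.26 and 1.91 on Het and unplaced sequence. The 10 longest combined-set clusters of this class all lay on 2R and 3L, and 9 of them within the blocks described above that reach past the first 1 Mb. The first was on 2R from 1119114 to 1195552 (76.4 kb, score 2.70), the second on 2R from 981230 to 1056426 (75.2 kb, score 2.41) and the third on 3L from 23417892 to 23491642 (73.8 kb, score 2.38). Each of the 10 was covered to more than 93% in both replicates. The 5 highest-scored distal clusters of the combined set were of another kind: they were 1001 to 2157 bp long, scored 3.68 to 5.18, and had no cluster in either replicate. They lay on 2R at 3758398 and 13063896, on 3L at 12916300 and on 3R at 1165476 and 20756588. The scores of those on 3L and 3R, 4.09 and 3.68, each recurred in other clusters.

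Beyond 2 Mb from the proximal ends, 1005 of 3559 combined-set clusters were covered to at least 50% in both replicates, and 57 of these were 10 kb or longer. X held 29 of the 57, 2R held 11, 2L and 3L held 8 each and 3R held 1. Of all combined-set clusters there, 300 of 1120 on X were covered to at least 50% in both replicates. The counts were 209 of 696 on 2R, 166 of 516 on 2L, 153 of 619 on 3L and 177 of 608 on 3R. The longest of the 57 lay on 2L from 20172692 to 20198604 (25.9 kb, score 2.04). A 24.0 kb cluster stood at the tip of X, from 80 to 24122 (score 2.00), and an 18.7 kb cluster stood near the tip of 3L, from 51096 to 69824 (score 2.14). The outermost 50 kb of X was covered to 53.8% and 56.3% in the replicates and that of 2L to 15.2% and 19.1%. The outermost 50 kb of 2R and 3L had no cluster in either replicate, and that of 3R was covered to 4.32% in replicate 1 and had no cluster in replicate 2.

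The distal X was covered more than the distal autosomes. In 1 Mb windows beyond 2 Mb, the mean coverage in replicate 1 was 7.11% ± 3.21 on X (SD, 20 windows) and 3.37% ± 2.22 on the autosomal arms (SD, 87 windows). In replicate 2 it was 10.5% ± 4.46 on X and 3.93% ± 2.38 on the autosomal arms. The ratio was 2.11 in replicate 1 and 2.66 in replicate 2, a mean of 2.38 ± 0.390 (SD, n = 2). Both differences passed a two-sided permutation test of the windows (adjusted p = 1e-05, the smallest that the permutations can give), although neighbouring windows are not independent. The test treats windows as the unit, but the X is a single arm, and the autosomal arms also differed among themselves. Among the autosomal arms, 2R had the highest mean, 4.70% and 5.56%, and 3R the lowest, 2.41% and 3.03%. With windows that started 1 Mb from the proximal ends, which take in the rest of the 2R and 3L blocks, the ratio was 1.78 and the permutation test was not passed (adjusted p = 0.10).

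**Figure D4:**
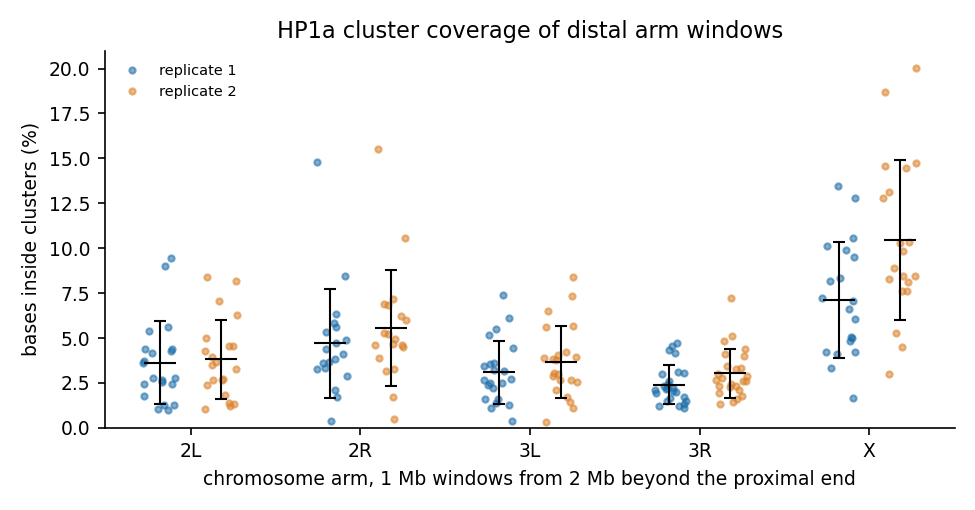
Share of bases inside HP1a clusters (percent, vertical axis) in each 1 Mb window that starts 2 Mb or more from the proximal end of an arm (horizontal axis), with a point for each window and replicate. Black bars give the mean and SD over windows, and the X means of 7.11% and 10.5% lie above those of the 4 autosomal arms.

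The second question was how far the replicates gave the same map. Of the clusters of replicate 1, 82.4% met a cluster of replicate 2, and 79.5% met one in the opposite direction, where shifted lists gave 44.6%. The Jaccard index of covered bases was 0.76, against a mean of 0.29 for lists shifted within each sequence (permutation test, adjusted p = 0.001, the smallest that the shifts can give). The index was 0.90 in the proximal class, where shifted lists gave a mean of 0.050. It was 0.58 on the distal arms, where they gave 0.046. In both classes the clusters were shifted along the whole arm, so most shifts moved proximal clusters onto thinly covered distal sequence. The value of 0.050 is therefore not the chance overlap inside the dense proximal blocks. The test cannot show that placement agreed within those blocks. On sequences covered densely throughout, shifted lists also overlapped. The index was 0.90 on chromosome 4 against 0.64, 0.83 on Het and unplaced sequence against 0.51, and 0.71 on YHet against 0.42. Each class passed the same permutation test (adjusted p = 0.001). On the distal arms, 79.8% of the clusters of replicate 1 met replicate 2 and 63.6% did so in the opposite direction. On distal X these shares were 83.3% of 522 clusters and 56.3% of 774 clusters.

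The scores of the replicates rose and fell together across 2558 combined-set clusters that met both (Spearman's rho 0.92, Pearson's r 0.91, across regions, which are not independent replicates). Within classes, rho was 0.93 in the proximal class, 0.81 on the distal arms, 0.73 on chromosome 4, 0.66 on Het and unplaced sequence and 0.47 over 24 regions of YHet.

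The third comparison was of the authors' combined set with the replicates it represents, on which it depends. It contained 99.999% of the bases covered in both replicates. Of its own bases, 66.8% lay in clusters of both replicates, 19.7% in those of 1 and 13.5% in those of neither. The share found in neither was 3.75% on chromosome 4, 6.29% in the proximal class, 6.23% on Het and unplaced sequence and 26.9% on the distal arms. By number, 1409 of the 3780 distal clusters of the combined set met neither replicate, and without these 2371 remained. Of the 1409, 741 were shorter than the shortest replicate cluster of 1301 bp.

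**Figure D5:**
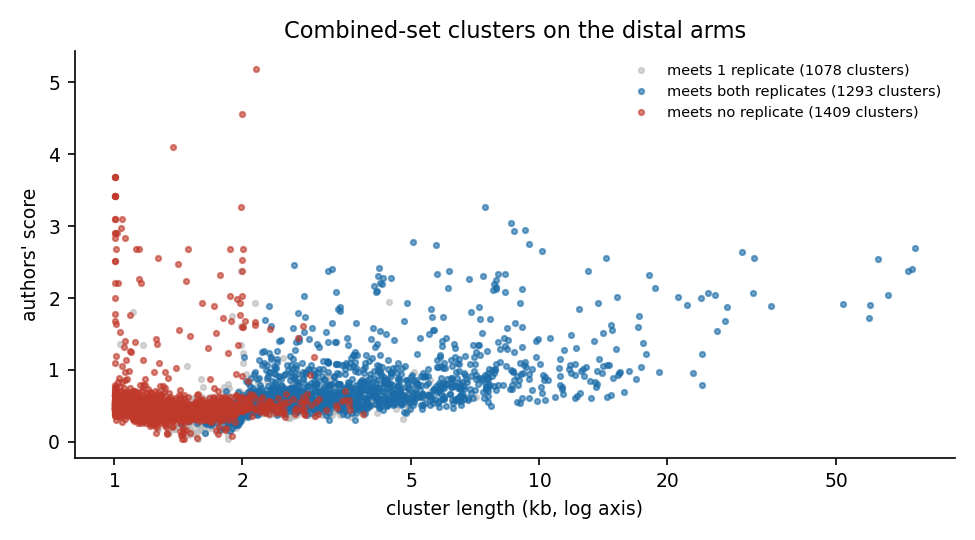
Authors' score (vertical axis, scale not stated) against length (kb, log axis) for each combined-set cluster on the distal arms, coloured by whether it meets both replicates (1293), 1 replicate (1078) or none (1409). Clusters that meet none reach the highest score, 5.18, at lengths of 1 to about 2 kb.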

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

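The X comparison and the combined set without unmatched clusters were chosen after the data had been seen, and the other alternatives before. A further 9 alternatives could not change their value by construction. Of the 48 that could, 36 held, 11 moved and 1 lost its call. A tested value held if it kept its direction and side of the threshold, a count if it stayed within 1.5 times, the share of combined clusters meeting both replicates and rho if they stayed within a 95% interval, and other values if they stayed within 1 SD of the replicates. No direction was reversed. Keeping only clusters at or above the median score shortened the lists by construction, to 2008 clusters and 18.1 Mb per replicate with a median length of 4528 bp, and left 253 distal clusters per replicate in place of 2034. Coverage of the distal arms was then 1.71% in place of 5.55%. The list medians of 1.35 and 1.09 lay above the distal medians of 0.75 and 0.74 in replicates 1 and 2. The cut therefore falls mostly on distal clusters by construction. A pericentric window of 2 Mb gave 41.5% in place of 57.6% for the proximal class and 4.65% in place of 5.55% for the distal arms. None of these coverage values lost its call. Merging clusters under 1000 bp apart raised the median length to 3083 bp and lowered the number of clusters per replicate from 4016 to 3099, below that of either replicate as deposited. A minimum length of 1000 bp removed no cluster and so tests nothing. Spearman's rho of the scores over all classes, 0.92, became 0.66 on Het and unplaced sequence, 0.93 in the proximal class, 0.73 on chromosome 4, 0.81 on the distal arms and 0.47 on YHet. The X to autosome ratio of 2.38 became 1.78 and lost its call with windows from 1 Mb, which by construction include the blocks of 2R and 3L. It was 3.95 with only distal clusters at or above the median distal score, which decides little, since the median distal score was higher on X. The 3780 distal clusters of the combined set became 2371 without those that met neither replicate. Each replicate alone gave 62.8% to 71.1% coverage for Het and unplaced sequence, 56.8% to 58.4% for the proximal class, 74.7% to 81.2% for chromosome 4, 5.06% to 6.05% for the distal arms, 50.7% to 70.5% for YHet and 2.11 to 2.66 for the X ratio, with no call changed. These calls repeat those already given for each replicate, and the replicates had given the same call each time. They add no further support, although they are counted among the 36 that held. The alternatives for gene bodies, gene lists and start sites were not run, for want of an annotation on r5. No paired analysis was possible because the input libraries had no region lists of their own here and each replicate list already sets a ChIP library against its input. The depth is unknown, so a missing distal cluster in 1 replicate does not show absence of binding there.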

Other observations

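All tests in this part were chosen after the result was seen. Beyond the pericentric blocks, separate HP1a-rich stretches recurred in both replicates within the first 3 Mb of several arms. On 2R the bins at 2100001 to 2200000 and 2300001 to 2400000 were covered to 43.4% and 55.2% in replicate 1 and to 42.9% and 46.8% in replicate 2, well past the end of the 1.6 Mb block. On 2L the bins at 21511545 to 21611544 and 20111545 to 20211544 were covered to 46.9% and 44.6% in replicate 1 and to 36.2% and 39.1% in replicate 2. On X the bin at 19522828 to 19622827 was covered to 27.5% and 41.4%. Between 1 and 3 Mb, no bin of 3R passed 16.2% in either replicate, and its highest was at 1400001 to 1500000.

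The 2 regions that the combined set names as depleted had scores of -0.03 and -0.04. The one on 3L, at 2599082 to 2600564, was 96.4% covered by enriched clusters of replicate 2 and 0% by those of replicate 1. The one on 2R, at 8902306 to 8904198, was 75.2% covered by enriched clusters of replicate 1 and 0% by those of replicate 2.

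The excess of HP1a clusters on the distal X, beyond 2 Mb from the proximal end, did not come only from calls that differ by chance between libraries: bases called in both replicates made up 5.79% of distal X, against a mean of 0.879% and a highest value of 1.43% over 1000 shifts within its windows (one-sided permutation p = 0.001, the smallest they can give), and 2.52% of the distal autosomes. Less the overlap that chance gives in each window, the ratio of X to the autosomes was 2.10 (two-sided permutation p = 1e-05, the smallest it can give). The windows are not independent here either, and the X is a single arm. A ChIP to input ratio raised along the whole X stays open. It could follow from a different share of X DNA in ChIP and input. The median score of distal-class clusters was 0.16 higher on X than on the autosomes, as a mean of the replicate differences. That class starts 1 Mb from the proximal ends and so takes in the rest of the 2R and 3L blocks. But the difference of XHet from the other Het scaffolds was -0.78 (scale not stated), and no values outside clusters were analysed. The labels give no group that would test a biological explanation.

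High scores in the combined set may partly reflect ratios of a few reads, which stays open. Of the 62 distal clusters with a score over 1.5 that met neither replicate, 90.3% had a score that recurred to 6 decimals in another cluster, against 9.35% of the 107 that met a replicate, but their median lengths were 1210 bp and 7327 bp. Of the 107, only 11 were no longer than 2771 bp, the longest of the 62, and 63.6% of these recurred (Fisher's exact test, two-sided, unadjusted p = 0.038, 1 of 4 such comparisons). Up to 2000 bp, all 52 that met neither and all 4 that met a replicate recurred, which decides nothing, and among those shorter than 1301 bp that met neither replicate, scores recurred in all 32 over 1.5 and in 46.5% of the 709 others (Fisher's exact test, two-sided, p = 5.3e-11). The 7 scores above 2.9 that at least 3 clusters shared, 61 clusters in all, were apart by log2 of ratios of the whole numbers 7, 8, 9, 10, 12, 14 and 16, within 0.001, and they include top-ranked scores on U, YHet and the distal arms; how many reads lie behind them was not measured.

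The doubled number of chromosome 4 clusters in replicate 2 did not come from binding at other places. Of its covered bases there, 99.0% lay inside clusters of replicate 1, which covered 81.2% of the chromosome, against a mean of 81.3% and a highest value of 98.5% over 1000 shifts along it (one-sided permutation p = 0.001, the smallest they can give). Merging clusters under 1000 bp apart lowered the ratio of the cluster numbers from 2.02 to 1.56, so breaks under 1000 bp account for part of it at most. Longer breaks inside replicate 1 clusters also occurred, which this merging cannot join. Within the replicate 1 cluster at 296519 to 343450, a replicate 2 cluster ended at 299625 and the next began at 301477. Longer breaks were not counted, and what caused the breaks stays open. Higher cluster numbers in replicate 2 were not confined to chromosome 4. They were 44 against 25 on YHet, 279 against 222 in the proximal class and 1749 against 1484 on Het and unplaced sequence. A difference in depth was not tested.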
